A study of Homo sapiens with 18 samples.

How the data were processed

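Gene expression was measured on 18 Affymetrix PrimeView arrays of human mesenchymal stem cells grown on 6 kinds of surface, 3 arrays per surface. The groups and replicate numbers were taken from the sample labels. Nothing in the labels says whether the replicates came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values (0 pairs).

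The deposited value table holds log2 expression levels for 49372 probe sets, from 1.735 to 14.78. Per the submitters' processing notes, R 2.15.0 and affy 1.34.0 were used; the summarization and normalization method is not given in the sources used here. The 95th percentiles of the deposited log2 values lay between 11.272 and 11.366 across arrays and the medians between 5.168 and 5.292, so the arrays share nearly one distribution. A change that moved most genes one way would be removed by such a scaling. The log2 values were used as deposited, with no further normalization and no filter on dim genes.

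Probe sets were named through GEO's platform annotation. Of the probe sets, 44988 had 1 gene symbol, 1832 had several and 2473 were unnamed here, and 79 were controls. Of the named probe sets, 44961 carried an identifier found in the RefSeq gene table used for current symbols, and 0 symbols changed. Probe sets with several genes and controls were left out, which gave 18132 genes, 11734 of them with more than 1 probe set. Each such gene was represented by the probe set with the highest mean over all arrays, and probe sets of one gene can disagree. Short probes can also read close paralogs and pseudogenes. A background level was set per array as the 95th percentile of 27 bacterial control probe sets, and it lay between 2.977 and 3.291 log2 units. A gene at or below it on every array of a group has only a bound there: its fold is given as "at least", the bright group's mean against the dim group's background, or its own level where that was higher. The mean level of 15097 genes lay above background. The number of arrays, rather than a count of molecules, limits the precision.

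Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (12 residual degrees of freedom, with an estimated 5.1 prior degrees of freedom), so that all groups share one estimate of spread per gene. Contrasts between groups, 2 interactions and an F test over the 6 groups were moderated with eBayes and adjusted by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05. Adjusted p-values in the text are limma's, two-sided, unless camera is named. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1, so single comparisons rest on limma's model. Fold errors are standard errors (SE), level errors are standard deviations (SD).

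A set of 34 gene lists was fixed before the data were examined, along with the comparisons, the tests, the alternative settings and the rule for naming genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists within a comparison, and again with a correlation estimated from the data. Fry was run beside camera; it tests whether a list's own genes move one way on balance and does not compare them with other genes. A list score is the mean, over members, of the log2 level minus the gene's mean over all arrays. Named genes are, per comparison, the 8 highest and the 8 lowest log2 fold changes among called genes whose groups do not overlap; all of them where there are fewer; where none passed, the 5 with the smallest p; the 3 members with the smallest p of each called list; the 2 members with the smallest p of the stem cell surface, osteogenic, adipogenic and chondrogenic lists; and FN1 in the fibronectin comparisons. Uncharacterized names were skipped, and not every gene the rule gives is described.

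The fit was tested on simulated data with the real gene means and spreads over 18132 genes. For ECM against TCP, limma recovered 49.3% of 67 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 100% of 66 changed 4-fold, with 5 false calls among 166. For ECM_FN against ECM the shares were 50.7%, 92.5% and 100%. For the interaction of matrix and cross-linker they were 9%, 67.2% and 100%. With nothing changed there were 0 calls in each. Camera called the list that had been shifted, and 0 others, in each simulation. The simulated genes varied independently of each other, with no technical difference between arrays. The simulations therefore do not show how often lists of correlated genes are called falsely. The genes changed in each were also a far smaller share than the 22.28% called for ECM vs TCP. Recovery depends on that share, so the percentages need not hold for the real comparisons.

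Replicate numbers repeat across groups. The correlations of same-numbered arrays' deviations from their group means were 0.11, 0.271 and 0.317 for ECM_FN against ECM, the one comparison where all exceeded a limit of 0.1. They were 0.239, 0.203 and 0.068 for TCP_Xlink against TCP, and in the other 5 comparisons at least 1 was below 0. Any such pairing comes from the data, not from a label. Blocking on the number left ECM_FN vs ECM at 0 calls and gave 46 for TCP_Xlink vs TCP.

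Other settings, fixed with the tests, were a filter on dim genes, quantile normalization, centring of arrays, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights, fits on only the groups compared, a replicate block, and leaving out each replicate in turn. After the control probe sets had been examined, 2 technical features were added as covariates or exclusions: RNA integrity, from the 3' minus 5' difference of the GAPDH controls, and a hybridization group of 3 arrays whose bioB controls averaged below 10 log2 units. Gene-by-gene array weights were added because the planned estimate of array weights stopped before converging. Other versions used were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.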

Results

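Human mesenchymal stem cells, adherent stromal progenitors that can form bone, fat and cartilage cells, were profiled on 6 culture surfaces. TCP was bare tissue culture plastic and TCP_Xlink was plastic treated with Sulfo-SANPAH, a light-activated cross-linker that couples proteins to surfaces. ECM was an extracellular matrix laid down by such cells and then stripped of them. The records give 7 days of culture, 8 days with 50 uM ascorbate, 0.5% Triton and 11 mM ammonium hydroxide for all matrix surfaces. None of these steps is given for plastic, so their effects cannot be told apart from those of the matrix. ECM_Xlink combined that matrix with the cross-linker, ECM_FN combined it with fibronectin, and ECM_Xlink_FN carried both additions. The ECM_FN surface is known from the sample labels alone, since the overall design text names the other 5 surfaces and not this one, and every comparison with ECM_FN rests on those labels. Each group held 3 arrays, and 18132 genes were tested. The comparisons ask how a cell-derived matrix changes expression relative to plastic, and whether cross-linking or fibronectin modifies this.

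The control probe sets separated a few arrays. The 3' minus 5' difference of the GAPDH controls, which grows as RNA is degraded, was 5.06 log2 units on TCP replicate 3 and 2.575 on TCP replicate 2, against 0.715 to 1.547 on the other 16 arrays. The bioB hybridization controls averaged 9.523 on TCP_Xlink replicate 1, 9.7 on ECM_Xlink replicate 1 and 9.577 on ECM_Xlink replicate 3, against 10.406 to 11.828 on the other 15. These 3 arrays are called the low-bioB group and the other 15 the main hybridization group. Within the main group ECM_Xlink_FN replicate 3 stood apart at 11.828, the rest lying between 10.406 and 11.003. The 18S ribosomal RNA control also set arrays apart. It stood at 10.047, 10.0 and 10.062 on TCP replicates 1, 2 and 3, against 10.438 to 10.955 on the other main-group arrays. On the low-bioB arrays it was 8.737 to 9.298. No setting used this level.

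**Figure D1:**
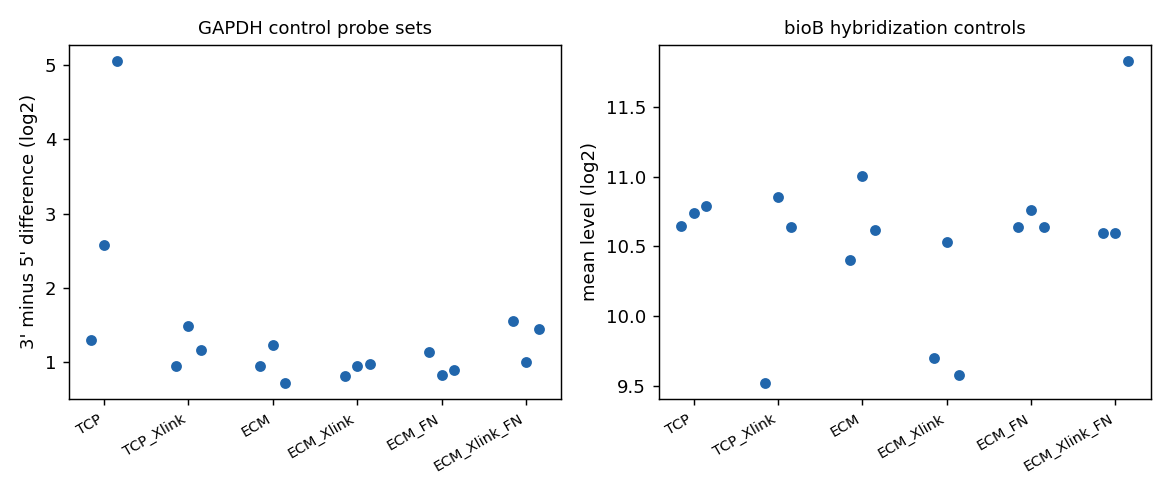
Control probe sets on each array (points), by surface: left, the GAPDH 3' minus 5' difference in log2 units; right, the mean level of the bioB hybridization controls in log2 units. TCP replicates 2 and 3 stand apart on the left at 2.575 and 5.06, and 3 arrays of TCP_Xlink and ECM_Xlink lie below 10 on the right.

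On matrix without cross-linker, APOC1, an apolipoprotein, was 15.4-fold higher on ECM than on TCP (log2 fold change 3.94 ± 0.27 SE, adjusted p = 7.65e-08). The chemokines CXCL3 and CXCL8 were 7.85-fold and 6.41-fold higher. The scavenger receptor COLEC12 was 6.9-fold higher, the complement component C7 6.69-fold, the chitinase-like protein CHI3L2 6.55-fold and the synaptic vesicle fusion protein SNAP25 6.24-fold. GSTM2P1 was 6.16-fold higher, but it is a pseudogene with close paralogs and its probe set may read those, and its level on TCP spread by 1.33 (SD, n = 3). In the other direction FLG, the epidermal protein filaggrin, lay below background on the 3 ECM arrays and was at least 16-fold lower there than on TCP (adjusted p = 2.65e-06). ELN, which encodes elastin, was 20.1-fold lower (level 6.43 ± 0.33 against 10.76 ± 0.16, SD, n = 3). INHBE, an inhibin subunit, was 14.4-fold lower, the peptide hormone gene ADM2 14.2-fold, the smooth muscle protein CNN1 9.15-fold, the basement membrane collagen COL4A4 8.81-fold, the tendon transcription factor MKX 8.26-fold and the surface glycoprotein CD24 8.07-fold. Each of these genes was also called without any one replicate.

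In all, limma called 4040 genes for ECM vs TCP, 1589 higher and 2451 lower on matrix, of which 623 differed at least 2-fold. Centring the arrays gave 1375 higher and 3011 lower. Over all 18132 genes, the 3 arrays of each group did not overlap for 6135 (33.84%); by chance 10% of genes would not overlap. For ECM vs TCP the count was 2628 without TCP replicate 3, the array with the largest GAPDH difference, to 1249 without TCP replicates 2 and 3, where the lone TCP array is assumed to vary like the others, and to 1506 with the GAPDH difference as a covariate.

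Mitotic genes had the highest share of called members of any list in this comparison. Of 23 measured members, 22 fell on ECM and none rose, with a median log2 fold change of -0.98 (camera adjusted p = 2.18e-18, and adjusted p = 0.048 with an estimated correlation). Adjusted over the list alone the count was also 22. The proliferation marker MKI67 fell 3.19-fold, the spindle checkpoint kinase BUB1 2.66-fold and CCNB1, cyclin B1, 1.96-fold. Without TCP replicates 2 and 3 the list's median was -0.82 and 19 members were called. Among the 21 measured DNA replication genes 7 fell and 1 rose (adjusted p = 0.0141, and adjusted p = 0.35 with an estimated correlation); the repair glycosylase UNG was the member that rose, by 1.59-fold.

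Genes for the matrix itself were lower on the cell-derived matrix. Of 29 glycoproteins and proteoglycans 16 fell and 2 rose, or 20 and 2 adjusted over the list alone (camera adjusted p = 4.94e-06, and adjusted p = 0.048 with an estimated correlation). Besides ELN, the cartilage matrix protein COMP was 4.3-fold lower and the proteoglycan ASPN 3.56-fold lower. Of 17 interstitial collagens 13 fell and 1 rose (adjusted p = 2.74e-05, and adjusted p = 0.099 with an estimated correlation), including COL8A2 by 3.82-fold and COL16A1 by 2.57-fold. Of 20 basement membrane genes 9 fell and 2 rose, among them COL4A2 and COL15A1 lower by 2.98-fold and 3.78-fold (adjusted p = 0.0119, and adjusted p = 0.19 with an estimated correlation); this was 0.0647 without TCP replicates 2 and 3 and 0.0603 with the mean of probe sets. Of 22 collagen processing genes 11 fell and 1 rose, with the lysyl oxidase LOXL4 3.41-fold lower (adjusted p = 0.00133, and adjusted p = 0.19 with an estimated correlation). Of 21 integrin and focal adhesion genes 10 fell and 1 rose, with the collagen receptor subunit ITGA11 4.02-fold lower (adjusted p = 0.00462, and adjusted p = 0.099 with an estimated correlation); this was 0.131 with the mean of probe sets. Of 15 contractile genes 7 fell and none rose, with ACTA2, smooth muscle actin, 2.38-fold lower and LMOD1 1.95-fold lower (adjusted p = 0.000701, and adjusted p = 0.048 with an estimated correlation).

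Inflammatory genes moved the opposite way. Of 21 cytokine and chemokine genes 11 rose on ECM and none fell, with a median log2 fold change of 0.54 (adjusted p = 6.06e-08, and adjusted p = 0.048 with an estimated correlation); CXCL1 was 2.69-fold higher. Of 22 interferon response genes 10 rose and 2 fell, with IFI44L 2.36-fold and OASL 2.09-fold higher (adjusted p = 0.000261, and adjusted p = 0.099 with an estimated correlation). Of 14 haematopoietic and macrophage markers 3 rose and 1 fell. The risers were HLA-DRA (4.4-fold) and CD74 (2.91-fold), which act in antigen presentation by major histocompatibility complex class II, and the lysosomal protein CD68 (1.65-fold). That list had adjusted p = 0.0102, and adjusted p = 0.099 with an estimated correlation.

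Among metabolic and stress genes, 10 of 18 hypoxia and glycolysis genes fell and 1 rose, with VLDLR 4.66-fold and ANKRD37 4.61-fold lower (adjusted p = 0.00462, and adjusted p = 0.11 with an estimated correlation). Of 18 unfolded protein and amino acid stress genes 8 fell and 2 rose, with asparagine synthetase, ASNS, 4.54-fold, the pseudokinase TRIB3 4.72-fold and the serine synthesis enzyme PHGDH 4.0-fold lower. That list had adjusted p = 0.0292, adjusted p = 0.35 with an estimated correlation, 0.131 without TCP replicate 1, 0.109 without ECM replicate 2, 0.0508 with arrays centred and 0.207 with the mean of probe sets. Of 10 epithelial markers 5 fell, KRT18 by 3.25-fold (adjusted p = 0.037, and adjusted p = 0.099 with an estimated correlation); this was 0.0844 without TCP replicate 1, 0.0519 without ECM replicate 2 and 0.0506 with arrays centred.

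With the cross-linker on both surfaces, many of the same genes separated matrix from plastic. BGLAP, the bone matrix protein osteocalcin, was 12.1-fold higher on ECM_Xlink than on TCP_Xlink (log2 fold change 3.6 ± 0.22 SE, adjusted p = 1.7e-08); its probe set may also read a readthrough transcript with its neighbour PMF1. The matrix protease MMP3 was 10.9-fold higher, CHI3L2 8.95-fold, SNAP25 8.26-fold, CCDC102B 7.75-fold and APOC1 7.22-fold. The class II antigen presentation genes HLA-DMB and HLA-DOA were 7.8-fold and 7.12-fold higher. INHBE was 21.1-fold lower, ELN 14.7-fold, COL4A4 13.1-fold, MKX 10.1-fold, ADM2 9.89-fold, RASSF2 9.22-fold and the amino acid transporter SLC7A5 7.44-fold lower. FLG lay below background on the ECM_Xlink arrays, at least 14.6-fold lower.

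Limma called 2501 genes for ECM_Xlink vs TCP_Xlink, 1352 higher and 1149 lower on ECM_Xlink, a majority that turned with arrays centred (1193 higher, 1247 lower). TCP_Xlink replicate 1 and ECM_Xlink replicates 1 and 3 belong to the low-bioB group, so the comparison was repeated with that group as a covariate, which gave 2276 calls. Within the main hybridization group it gave 869 and within the low-bioB group 918. Each of these has 1 array on one side, ECM_Xlink replicate 2 or TCP_Xlink replicate 1, which is assumed to vary like the others, and their arrays also took part in the 2501 calls.

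Matrix glycoproteins fell again (11 of 29, with 1 higher; adjusted p = 2.37e-08, and adjusted p = 0.038 with an estimated correlation), as did contractile genes (6 of 15; adjusted p = 5.9e-05, and adjusted p = 0.038 with an estimated correlation). Of the mitotic genes 13 of 23 were called lower, with a median log2 fold change of -0.38 (adjusted p = 2.37e-08, and adjusted p = 0.11 with an estimated correlation). The 13 became 6 without TCP_Xlink replicate 2, 7 without ECM_Xlink replicate 1, 8 without ECM_Xlink replicate 2 and 3 within the main hybridization group, with medians from -0.34 to -0.54. Of the interstitial collagens 9 of 17 fell, COL11A1 by 5.34-fold, and 1 rose (adjusted p = 5.21e-05, and adjusted p = 0.083 with an estimated correlation). Of 22 collagen processing genes 5 fell (adjusted p = 0.00146, and adjusted p = 0.18 with an estimated correlation). Of 18 unfolded protein and amino acid stress genes 9 fell (adjusted p = 2.98e-06, and adjusted p = 0.074 with an estimated correlation), and of 18 hypoxia genes 8 fell (adjusted p = 9.75e-05, and adjusted p = 0.074 with an estimated correlation). Inflammatory genes rose in 8 of 21 cases, with CXCL1 2.89-fold higher (adjusted p = 0.000275, and adjusted p = 0.083 with an estimated correlation), and interferon genes in 8 of 22, with OASL 3.29-fold higher (adjusted p = 5.21e-05, and adjusted p = 0.083 with an estimated correlation). Replication genes fell in 4 of 21 cases (adjusted p = 0.0126, and adjusted p = 0.31 with an estimated correlation; 0.0871 without TCP_Xlink replicate 2).

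Camera called 4 further lists for ECM_Xlink against TCP_Xlink and not for ECM against TCP; none of the 4 was called in the interaction of matrix and cross-linker, so a difference between both states was not shown. Of these, 7 of 16 NRF2 targets, genes of the oxidative stress response, rose and 2 fell, with the haem oxygenase HMOX1 2.52-fold and AKR1C1 2.57-fold higher, though AKR1C1 has near-identical paralogs (adjusted p = 0.00399, and adjusted p = 0.074 with an estimated correlation). Of 22 YAP and TAZ targets 6 fell and 1 rose, with the tissue factor F3 2.54-fold lower (adjusted p = 0.0183, and adjusted p = 0.083 with an estimated correlation). Of 13 TGF-beta targets 4 fell, PMEPA1 by 2.62-fold (adjusted p = 0.032, and adjusted p = 0.083 with an estimated correlation); this was 0.111 without TCP_Xlink replicate 1 and 0.108 without ECM_Xlink replicate 2. Of 14 respiratory chain genes 1 rose, SDHA by 1.43-fold (adjusted p = 0.00439, and adjusted p = 0.2 with an estimated correlation).

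The comparisons with and without cross-linker share no arrays. Across all 18132 genes their log2 fold changes correlated with Pearson r = 0.677 and Spearman rho = 0.452; genes are not independent replicates. Both called 710 genes higher on matrix, against 118 expected for independent lists, and 840 lower, against 155 expected. In opposite directions 11 genes were called. Since both use the same estimate of spread per gene, the lists are not independent and the expected counts may be too low. Averaged over both cross-linker states, 4590 genes differed between matrix and plastic, 2108 higher and 2482 lower, or 1819 and 3016 with arrays centred. In that average HLA-DRA was 5.02-fold higher on matrix (adjusted p = 1.97e-11), HMOX1 2.79-fold higher and the cystine transporter SLC7A11 5.75-fold lower. Camera called 16 lists for the average, 2 of them with an estimated correlation, the matrix glycoproteins and the contractile genes (adjusted p = 0.041 each). The haematopoietic list had a median of 0.0 there but a mean of 0.36, and its adjusted p was 0.0389, or 0.0625 without ECM replicate 3.

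**Figure D2:**
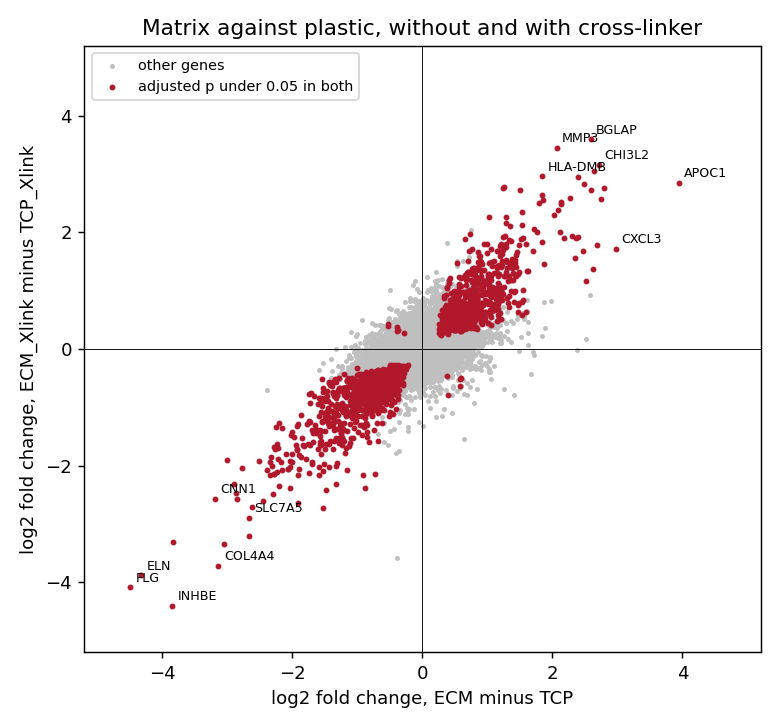
Log2 fold change of each gene on ECM minus TCP (horizontal) and ECM_Xlink minus TCP_Xlink (vertical); red points are genes with an adjusted p under 0.05 in both. Most red points lie in the lower left (840 genes) and upper right (710 genes), and 11 lie in the other 2 quadrants.

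Between matrix and plastic, with or without cross-linker, camera called none of the mesenchymal surface, osteogenic, adipogenic and chondrogenic marker lists. Camera compares a list with the other genes. Fry, which tests only whether a list's own genes move one way on balance, gave an adjusted p under 0.05 for some of them. Of 18 mesenchymal surface markers 2 rose and 6 fell on ECM (camera adjusted p = 0.0538, fry 0.000107), with the adhesion proteoglycan CSPG4 2.93-fold and the sialomucin PODXL 2.4-fold lower. On ECM_Xlink 4 rose and 4 fell (camera adjusted p = 0.767, fry 0.394). Of 14 osteogenic markers 4 rose and 3 fell on ECM (camera adjusted p = 0.342, fry 0.0269; median 0.0, mean 0.16), and BGLAP and the growth factor BMP2 were 6.01-fold and 2.22-fold higher. On ECM_Xlink 3 rose and 3 fell (camera adjusted p = 0.285, fry 0.000578). Of 16 adipogenic markers 4 rose and 3 fell on ECM (camera adjusted p = 0.362, fry 0.121), with the transcription factor CEBPA 1.85-fold higher; on ECM_Xlink 6 rose and 1 fell (camera adjusted p = 0.128, fry 0.000297), with PPARG, the master regulator of fat cell differentiation, 2.81-fold higher. Of 15 chondrogenic markers 2 rose and 5 fell on ECM (camera adjusted p = 0.671, fry 0.0103), with COL10A1 4.02-fold and HAPLN1 3.45-fold lower. On ECM_Xlink 2 rose and 3 fell (camera adjusted p = 0.203, fry 0.00811).

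Mitotic genes were higher on cross-linked matrix than on matrix without cross-linker. Against plain ECM, 16 of 23 members rose on ECM_Xlink and none fell, or 21 adjusted over the list alone, with a median log2 fold change of 0.7 (camera adjusted p = 4.31e-31, and adjusted p = 0.02 with an estimated correlation). The 16 became 7 without ECM_Xlink replicate 3, with a median of 0.65, and 7 without ECM replicate 3, with a median of 0.67. BUB1 was 2.34-fold and CCNB1 1.76-fold higher, and the kinetochore gene SKA3, outside the list, 2.2-fold higher. With fibronectin present, 19 of 23 rose on ECM_Xlink_FN against ECM_FN and none fell, or 22 adjusted over the list alone, with a median of 0.87 (adjusted p = 2.47e-59, and adjusted p = 0.0012 with an estimated correlation). BUB1 was 2.75-fold higher, MKI67 2.4-fold, and 4 further cell division genes, ASPM, KIF14, CDKN3 and PBK, were 2.29-fold to 2.6-fold higher. The mean mitosis score was -0.64 ± 0.14 on ECM, -0.56 ± 0.03 on ECM_FN, 0.06 ± 0.11 on ECM_Xlink, 0.31 ± 0.11 on ECM_Xlink_FN, 0.34 ± 0.09 on TCP and 0.48 ± 0.09 on TCP_Xlink (SD, n = 3). With the low-bioB group as a covariate the median for ECM_Xlink against ECM was 0.66 with 5 members called, and within the main hybridization group it was 0.66 with 0 called over all genes, where ECM_Xlink keeps 1 array that is assumed to vary like the others. All 6 arrays with fibronectin lie in the main hybridization group, though ECM_Xlink_FN replicate 3 had the highest bioB level of any array, 11.828. Without that array the list's median for ECM_Xlink_FN against ECM_FN was 0.85 with 17 members called.

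**Figure D3:**
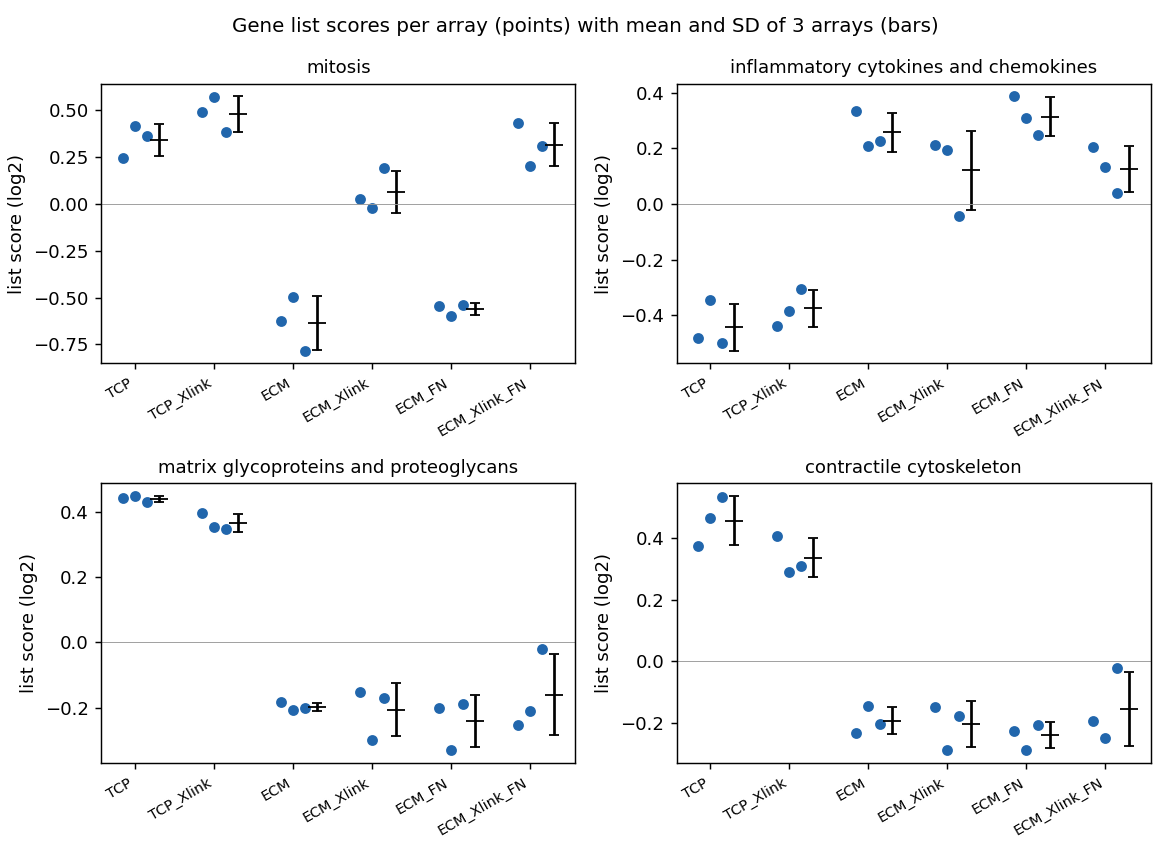
Scores of 4 gene lists on each array (points; vertical axes in log2 units, each list on its own scale), with the mean and SD of the 3 arrays of a surface (bars). Mitotic genes are lowest on ECM and ECM_FN, at means of -0.64 and -0.56, while the matrix and contractile lists separate both plastic surfaces from the 4 matrix surfaces.

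Other genes that moved with the cross-linker on matrix differed in function. On ECM_Xlink the flavin monooxygenase FMO2 was 4.63-fold lower (log2 fold change -2.21 ± 0.19 SE, adjusted p = 2.26e-05) and the WNT antagonist SFRP4 2.68-fold lower. SHISA2 was 2.4-fold and the transcription factor FOXQ1 2.26-fold higher. PODXL rose by a log2 fold change of 1.1 ± 0.12 SE on ECM_Xlink_FN against ECM_FN. PODXL in ECM_Xlink vs ECM was 1.61-fold higher, with an adjusted p of 0.00705 that became 0.0655 without ECM_Xlink replicate 3, and it was not called with the low-bioB group as a covariate. The protease MMP1 was 2.79-fold higher on ECM_Xlink_FN, and the transporter SLCO4C1 was lower in both comparisons, 2.2-fold and 1.91-fold. In total 170 genes were called for ECM_Xlink against ECM, 120 higher and 50 lower, and 94 for ECM_Xlink_FN against ECM_FN, 81 higher and 13 lower. These comparisons share no arrays. Both called 47 genes higher, against 0.536 expected for independent lists, 4 lower, against 0.0358 expected, and 0 in opposite directions. They use the same estimate of spread per gene, so the lists are not independent and the expected counts may be too low.

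The count for ECM_Xlink vs ECM moved with the setting and with single arrays. With the low-bioB group as a covariate 36 genes were called, and within the main group, with 1 ECM_Xlink array assumed to vary like the others, 2. Without ECM_Xlink replicate 2, its one array in the main group, 778 were called; without replicate 1 the count was 75 and without replicate 3 it was 39, and without ECM replicates 1 and 3 it was 95 and 48. The 94 calls for ECM_Xlink_FN vs ECM_FN became 47 without ECM_Xlink_FN replicate 1 and to 60, 51 and 49 without ECM_FN replicates 1, 2 and 3. Lists of 3 further kinds were called for ECM_Xlink against ECM, surface markers up (adjusted p = 0.022), trophic factors up (adjusted p = 0.0297) and cholesterol synthesis down (adjusted p = 0.0385), each with adjusted p = 0.39 with an estimated correlation. With the low-bioB group as a covariate the surface list had 0.155 and the trophic list 0.0755, and with quantile normalization both had 0.0554. The trophic list had 0.0753 without ECM_Xlink replicate 2, 0.0697 without ECM replicate 2 and 0.793 with the mean of probe sets, where its median was 0.06 against 0.18. The cholesterol list had 0.311 without ECM_Xlink replicate 2, 0.074 without ECM replicate 1 and 0.0891 without ECM replicate 3. With fibronectin they were replication genes up (adjusted p = 8.81e-05; adjusted p = 0.44 with an estimated correlation), and inflammatory genes (adjusted p = 0.000327; adjusted p = 0.24 with an estimated correlation) and cholesterol synthesis (adjusted p = 2.93e-05; adjusted p = 0.12 with an estimated correlation) down, with no single member called in these 3.

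On plastic the number of genes that passed with the cross-linker depended on single arrays. Limma called 13 for TCP_Xlink vs TCP, 7 higher and 6 lower, while 3040 had an unadjusted p under 0.05 where 907 would be expected. The lipid synthesis enzyme GPAM was 2.37-fold higher (log2 fold change 1.25 ± 0.21 SE, adjusted p = 0.0295), the amino acid transporter subunit SLC3A1 2.32-fold and TM4SF4 2.1-fold, while the matrix proteins SPON2 and OLFML2B were 1.65-fold and 1.54-fold lower. The comparison sets TCP, with its 2 arrays of high GAPDH difference, against TCP_Xlink. With that difference as a covariate 0 genes were called, as without TCP replicate 2, TCP replicate 3, TCP_Xlink replicate 2 or TCP_Xlink replicate 3, and without TCP replicate 1 the count was 1487. With the low-bioB group as a covariate it was 294, and within the main hybridization group 41. Quantile normalization gave 27 higher and 61 lower, and centring 14 higher and 76 lower. The mitosis list was called upward with 0 of 23 members past the threshold (median 0.05; adjusted p = 0.008, and adjusted p = 0.54 with an estimated correlation). It had 0.077 without TCP_Xlink replicate 2 and 0.172 without TCP replicate 1.

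The comparisons of fibronectin called few genes. For ECM_FN vs ECM limma called 0 genes, and 463 had an unadjusted p under 0.05 where 907 would be expected by chance. Gene-by-gene array weights gave 1. FN1, the gene for fibronectin, stood at 13.15 ± 0.05 on ECM_FN and 13.18 ± 0.04 on ECM (SD, n = 3). The smallest p belonged to PDZD7, with a log2 fold change of -0.72 ± 0.14 SE that did not pass. TXNIP, a thioredoxin inhibitor, had -0.86 ± 0.19 SE and did not pass. Camera called 6 lists with medians no further from 0 than 0.13 and with no member past the threshold. They were replication, mitosis, trophic factors and hypoxia up and cholesterol synthesis down (adjusted p = 0.0258 each), and collagen processing up (adjusted p = 0.0451). Their adjusted p was 0.46 to 0.61 with an estimated correlation. Without ECM_FN replicate 3 it was 0.207 or more for each, and without ECM replicate 1 or 3 none was called, with values from 0.052 to 0.676. Trophic factors were also not called without ECM_FN replicate 1 (0.082) or ECM replicate 2 (0.258), nor collagen processing without ECM_FN replicate 1 (0.134). For ECM_Xlink_FN vs ECM_Xlink 1 gene was called, CST1, a secreted protease inhibitor, 1.82-fold lower on ECM_Xlink_FN (adjusted p = 0.00944), and the call ended without ECM_Xlink replicate 1 or 3 or ECM_Xlink_FN replicate 1 or 3, and with the low-bioB group as a covariate. Without ECM_Xlink replicate 2 the count was 196. In that comparison 2417 genes had an unadjusted p under 0.05 where 907 would be expected, so smaller differences are not excluded, and 2 of its 3 ECM_Xlink arrays are in the low-bioB group. Mitotic genes had a median of 0.27 there, with 0 members past the threshold over all genes and 6 adjusted over the list alone (camera adjusted p = 1.6e-06, and adjusted p = 0.64 with an estimated correlation). Camera also called replication genes up (median 0.24, adjusted p = 0.0217; adjusted p = 0.78 with an estimated correlation), and trophic factors (adjusted p = 0.0489) and cholesterol synthesis (adjusted p = 0.0425) down, each with a median of -0.16 and adjusted p = 0.64 with an estimated correlation. With the mean of probe sets these 3 had 0.31, 0.837 and 0.326, and the trophic median was 0.05. The low-bioB covariate ended 2 of the calls, with medians of -0.08 for trophic factors (camera adjusted p = 0.194) and -0.03 for cholesterol synthesis (0.553). None of the 3 was called without ECM_Xlink replicate 1 (0.061, 0.0632 and 0.0632), ECM_Xlink replicate 2 (0.17, 0.17 and 0.0928) or ECM_Xlink_FN replicate 1 (0.162, 0.0553 and 0.162), nor the last 2 without ECM_Xlink_FN replicate 2 (0.0631 and 0.0517), nor trophic factors without ECM_Xlink_FN replicate 3 (0.278).

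The interaction tests asked whether the cross-linker acted differently on matrix and plastic, or with and without fibronectin. For the interaction of matrix and cross-linker 17 genes were called, 12 higher and 5 lower. BUB1 was among them, with a log2 difference of fold changes of 1.24 ± 0.19 SE (adjusted p = 0.0231), as were FOXQ1 (1.52 ± 0.25) and CCNB1 (0.83 ± 0.13) upward, and FMO2 (-1.57 ± 0.27) and SFRP4 (-1.36 ± 0.23) downward. The count was 0 without TCP replicate 2 or 3, TCP_Xlink replicate 3, ECM replicate 1 or 3, or ECM_Xlink replicate 3, and 0 with the GAPDH difference as a covariate or within the main hybridization group. It was 9 without TCP_Xlink replicate 2 or ECM_Xlink replicate 1, 33 without ECM replicate 2, 58 without TCP_Xlink replicate 1, 448 without ECM_Xlink replicate 2 and 757 without TCP replicate 1. For fibronectin and cross-linker limma called 0 genes, with 1135 at an unadjusted p under 0.05 where 907 would be expected; gene-by-gene array weights gave 1. An F test over the 6 groups called 4036 genes.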

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

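The tests of the mitosis pattern and the checks that used the hybridization group and the GAPDH difference as covariates or exclusions were chosen only after the results were seen; the other tests were written down before their results, except that their second sets of arrays were added later, before the values were seen.

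A difference between surfaces in the response to the cross-linker drew attention, since the interaction of matrix and cross-linker called 17 genes. Of 100 splits of the arrays, cross-linker against none within each surface, 6 gave as many, and the highest of the others gave 1220, so chance is not excluded. That split exchanged TCP_Xlink replicate 1 with TCP replicate 1 and ECM_Xlink replicate 2 with ECM replicate 2. It thus put all low-bioB arrays, and both TCP arrays of high GAPDH difference, on one side of the contrast. A count so far above the real one points to these technical features, which the split cannot tell apart. Mitotic genes had a median interaction of 0.56 and mesenchymal surface markers 0.25, while inflammatory genes had -0.18; the adjusted p was 0.42 for each with an estimated correlation. The surface markers were no longer called without TCP_Xlink replicate 2 (0.0997), ECM_Xlink replicate 3 (0.0851), ECM replicate 2 (0.064) or TCP replicate 1 (0.102), nor the inflammatory genes without ECM_Xlink replicate 3 (0.0851), ECM replicate 1 (0.118) or TCP replicate 1 (0.0947). With the mean of probe sets the medians were 0.34 for mitosis, still called, 0.03 for the surface markers (0.457) and -0.27 for the inflammatory genes (0.0529). Surface markers were also not called over genes above the median level (0.144), with the hybridization covariate (0.0751) or in the main hybridization group (0.0791), nor inflammatory genes in that group (0.0699). For fibronectin and cross-linker, mitotic genes had a median interaction of 0.2 (adjusted p = 0.9 with an estimated correlation) and trophic factors -0.22 (adjusted p = 0.28 with an estimated correlation), or -0.05 with the mean of probe sets, where they were not called (0.273). The mitosis call was lost without ECM_Xlink replicate 1 (0.0626) or 2 (0.349), ECM_Xlink_FN replicate 1 (0.372), ECM_FN replicate 2 (0.0559), or ECM replicate 1 (0.0966) or 2 (0.281). That interaction called 0 genes with limma (1135 at an unadjusted p under 0.05), and since every one of the 100 splits gives at least 0, the splits decide nothing about that count. The highest other gave 81. That split exchanged all ECM_Xlink arrays with all ECM arrays, and ECM_Xlink_FN replicate 3 with ECM_FN replicate 1. It thus largely adds the cross-linker differences of both fibronectin states instead of contrasting them. Its count is therefore no sign of an unknown structure of the samples.

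Control probe sets, which no comparison uses, showed several signals. The 18S ribosomal RNA control was 10.0 to 10.062 on the TCP arrays, 10.438 to 10.955 on the other main-group arrays and 8.737 to 9.298 on the low-bioB arrays. The GAPDH 3' minus 5' difference was 5.06 on TCP replicate 3 and 2.575 on TCP replicate 2. The bioB controls averaged 9.523 on TCP_Xlink replicate 1, 9.7 on ECM_Xlink replicate 1 and 9.577 on ECM_Xlink replicate 3.

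The first pattern is the difference between matrix and plastic without cross-linker, where RNA degradation on TCP replicates 2 and 3 could raise or lower genes by where their probes lie. Genes called higher on ECM kept 57.9% of their median difference in ECM_Xlink replicate 2 against TCP_Xlink replicates 2 and 3. They kept 58.3% in the low-bioB arrays of the same surfaces. None of these arrays had a high GAPDH difference, which argues against degradation as the whole cause for the genes called higher. The first set holds a single ECM_Xlink array and the second a single TCP_Xlink array, which limits this for both directions. Genes called lower kept 59.1% in the first set, past the bound of 50% set beforehand, but only 40.5% in the second, and the first rests on a single ECM_Xlink array, so part of that side stays open. Genes called for ECM_Xlink against TCP_Xlink kept 80.4% of their signed median difference in ECM against TCP replicate 1, and 79.9% against all TCP arrays, which argues against the hybridization group as the whole cause. An effect of the matrix itself remains a hypothesis.

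The second pattern is the set of 170 genes called for ECM_Xlink vs ECM, where 2 of the 3 ECM_Xlink arrays have low bioB controls and all ECM arrays do not. These genes kept 86.1% of their signed median difference in ECM_Xlink replicate 2 alone, an array that also entered their selection, and 58.8% in ECM_Xlink_FN against ECM_FN, 6 other arrays of the main hybridization group. That argues against the hybridization group as the whole cause for the set, though ECM_Xlink_FN replicate 3 had the highest bioB level, 11.828. Single genes stay open: with the group as a covariate 36 genes were called, and the cause of that drop was not tested.

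The third pattern is the rise of mitotic genes with the cross-linker on matrix. In ECM_Xlink_FN against ECM_FN, all in the main hybridization group, the list's median difference was 123.7% of that in ECM_Xlink against ECM, and 0 of 9 pairs of arrays had a median below 0, which argues against the hybridization group. GAPDH differences of the cross-linked matrix arrays (0.804 to 1.547) overlapped those of the others (0.715 to 1.231). Those of ECM_Xlink (0.804 to 0.978) lay within those of ECM (0.715 to 1.231), which argues against RNA degradation there. Those of ECM_Xlink_FN (1.0 to 1.547) overlapped those of ECM_FN (0.829 to 1.132) only in part, so degradation stays open there. With the difference as a covariate 98.3% of the median was left in one comparison and 100.3% in the other. Its slope is fitted over all 18 arrays, with the widest spread on TCP, so these shares decide little. A candidate explanation is that more cells were dividing on cross-linked matrix when RNA was taken; cell number, confluence and time of harvest were not analysed here and stay open.

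Splits of the samples bear on the counts as follows. Averaged over cross-linker states, matrix against plastic called 4590 genes, and 1 of 100 splits, the real one, gave as many (highest other 2432). A random grouping of these arrays thus rarely gave so many calls. The arrays of a surface may be technical replicates, so chance differences between single cultures are not excluded. The highest other exchanged TCP_Xlink replicate 1 with ECM_Xlink replicate 2 and so followed the hybridization groups among the cross-linked arrays. It kept the real labels of ECM and TCP, so their difference also entered the 2432. The F test called 4036 genes, and 1 of 100 regroupings, the real one, gave as many (highest other 417), with the same limit on chance. Comparisons of 3 arrays against 3 have 10 splits, too few for a share under 0.05. The real counts and the highest others were 4040 and 956 for ECM against TCP, 2501 and 1004 for ECM_Xlink against TCP_Xlink, 13 and 0 for TCP_Xlink against TCP, 170 and 8 for ECM_Xlink against ECM, 94 and 1 for ECM_Xlink_FN against ECM_FN, 0 and 0 for ECM_FN against ECM, and 1 and 0 for ECM_Xlink_FN against ECM_Xlink. For ECM_Xlink against TCP_Xlink the 1004 came from the split that sets the low-bioB arrays against the rest.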

How the results depend on the processing

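The gene-by-gene array weights and all settings that use the hybridization group or the GAPDH difference were chosen after the data were seen. The pseudocount setting was not run, since the values are log2 levels. A low signal over background limits dim genes, whose folds are bounds.

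No called named gene reversed its sign, and no called list the direction of its test, in any setting that was run. The median of the trophic list, -0.16 for ECM_Xlink_FN vs ECM_Xlink, was 0.05 with the mean of probe sets, where it was not called (0.837), and that of the haematopoietic list for ECM average vs TCP average went from 0 to -0.01 there and with the hybridization covariate. Of 255 calls of named genes, 253 were kept with quantile normalization, 254 with centring and 225 with the mean of probe sets. The hybridization covariate kept 239 and the GAPDH covariate 224. The main hybridization group alone, and leaving out TCP replicates 2 and 3, kept a smaller share. Both leave a single array in a group. Most named genes were chosen for large folds or small p-values in these same arrays, so the shares kept do not describe all calls. Counts over all genes are given below. Of 68 list calls, 10 were kept with an estimated correlation, 51 with fry and 52 with the mean of probe sets. Quantile normalization kept 61, and a fit of genes above the median level 50. Over genes above the median level, the calls lost for ECM vs TCP were replication (0.0521), basement membrane (0.0724), epithelial markers (0.281) and amino acid stress (0.0867), and for ECM_Xlink vs TCP_Xlink NRF2 targets and inflammatory genes (0.0562 each). Where a count below differs from that reported, the cause was not tested.

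TCP_Xlink vs TCP (13) had 112 calls over genes above the median level, 88 with quantile normalization, 90 with centring, 4 with the mean of probe sets, 82 with a trend and robust prior, 46 with the replicate block and 0 in a fit of only its groups. The hybridization covariate gave 294, the main hybridization group 41, the GAPDH covariate 0 and leaving out TCP replicates 2 and 3 0.

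The interaction of matrix and cross-linker (17) had 81, 34, 38, 11 and 69 calls under the first 5 of these settings, and 0 in the main hybridization group, with the GAPDH covariate and without TCP replicates 2 and 3. ECM_Xlink_FN vs ECM_Xlink (1) had 0 over genes above the median level, 0 in a fit of only its groups, 0 with the hybridization covariate and 0 in the main hybridization group.

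A fit of only the groups compared gave 66 for ECM_Xlink vs ECM (170) and 47 for ECM_Xlink_FN vs ECM_FN (94). ECM_Xlink vs ECM had 36 with the hybridization covariate and 2 in the main hybridization group. ECM_Xlink vs TCP_Xlink (2501) had 869 in that group and 918 in the low-bioB group. ECM vs TCP (4040) had 1506 with the GAPDH covariate and 1249 without TCP replicates 2 and 3, and any difference among the 6 groups (4036) had 2588 and 2472.

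Array weights stopped before converging and gave TCP replicate 2, an array with a high GAPDH difference, a weight of 20.2, against 2.99 gene by gene, so neither set of counts carries a statement here. With array weights, and then gene by gene, the calls were 9485 and 6526 for ECM vs TCP, 6013 and 5109 for ECM_Xlink vs TCP_Xlink, 8830 and 7066 for ECM average vs TCP average, 5496 and 1892 for TCP_Xlink vs TCP, 4388 and 2934 for ECM_Xlink vs ECM, 265 and 243 for ECM_Xlink_FN vs ECM_FN, 1 and 1 for ECM_FN vs ECM, 2398 and 918 for ECM_Xlink_FN vs ECM_Xlink, 5777 and 3329 for the interaction of matrix and cross-linker, 3 and 1 for the interaction of fibronectin and cross-linker, and 13574 and 9106 for any difference among the 6 groups.

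Leaving out 1 replicate at a time gave 2628 to 4600 calls for ECM vs TCP, 0 to 1487 for TCP_Xlink vs TCP, 39 to 778 for ECM_Xlink vs ECM, 47 to 87 for ECM_Xlink_FN vs ECM_FN, 0 to 196 for ECM_Xlink_FN vs ECM_Xlink and 0 to 757 for the interaction of matrix and cross-linker. The other results stayed within 1.5 times their count: 1686 to 2695 for ECM_Xlink vs TCP_Xlink, 3966 to 4993 for ECM average vs TCP average, 3105 to 4780 for any difference among the 6 groups, and 0 for ECM_FN vs ECM (463 genes at an unadjusted limma p under 0.05 with all arrays) and for the interaction of fibronectin and cross-linker (1135).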

Other observations

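HLA-DRA, an antigen presentation gene, stood at 11.22 ± 0.14 on the 6 matrix arrays without fibronectin and 8.89 ± 0.14 on the 6 plastic arrays (SD, n = 6), with no overlap. CD74, the class II invariant chain, stood at 11.3 ± 0.17 and 9.58 ± 0.16. Probe sets for HLA genes can depend on the alleles of the cells. The cystine transporter SLC7A11 stood at 8.19 ± 0.25 on matrix and 10.72 ± 0.18 on plastic, while 7 of the 16 NRF2 targets on its list were called higher and 2 lower.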
